A study of Arabidopsis thaliana with 18 samples.

How the data were processed

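Transcript levels were measured in roots of Arabidopsis thaliana on 18 Affymetrix ATH1 arrays of 1 colour. Per the labels, 3 genotypes were grown at 2 iron supplies with 3 biological replicates in each of the 6 groups. Per the labels' protocols, total RNA was extracted with a Qiagen RNeasy kit, and biotin-labelled RNA was made from it by in vitro transcription. Each sample's genotype, supply and replicate number were taken from its label, and all 18 columns of the deposited table were matched to a sample.

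The deposited values are 1 linear signal intensity per probe set and array, made by the authors from the scanned arrays. The software that summarised them is not given in the sources used here. The arrays had 2% trimmed means that were nearly equal, medians from 189.9 to 211.3, and signals from 0 to 36319.7; they had been scaled but not quantile normalized. No detection calls were used, so a value near 0 has no stated limit of detection.

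The table held 22810 probe sets. The 64 control probe sets were set aside and 22746 were tested. By the platform annotation, 13513 of these named 1 gene, 503 several and 8730 none. A probe set without a name here is unnamed, not without a gene, and no gene was named from a probe set with several. Names were updated with the RefSeq gene table of the TAIR10.1 assembly, which matched 13436 of them by Entrez number. The array values name no genome build, so no coordinates are given. In all 13286 genes were measured, and where a gene had several probe sets the one with the highest mean over all arrays stood for it in gene lists.

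Values were taken as log2(signal + 16), and every fold change is on that scale, which understates the change of dim genes. The 6 group means were fitted over all 18 arrays with limma 3.58.1 in R 4.3.3, with moderated variances and 12 residual degrees of freedom. Each of 9 contrasts was adjusted by the Benjamini-Hochberg method, and a probe set was called at an adjusted p under 0.05. The contrasts were the Fe response of each genotype, the difference of each other genotype from Col-0 at each supply, and the difference of its Fe response from that of Col-0. The p-values measure the spread between these samples, which are biological replicates per the labels. Adjusted p-values in the text are from limma, and those of gene lists from limma's camera with a preset correlation of 0.01, adjusted over the lists of a comparison. A list needed 3 measured genes. Where a list was called, the p with an estimated correlation stands beside it. Principal components were computed in R, and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

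The samples, the main fit of each comparison, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. Per Fe response the rule took the 8 rising and 8 falling genes with the greatest change among probe sets that were called, named 1 gene and had values of the 2 groups that did not overlap, which chance gives for 10% of probe sets with 3 against 3. Per genotype comparison and per difference it took 6 and 6, without the overlap condition for differences. It added up to 4 members of each fixed list and UBC35, UBC36, FIT, IRT1, FRO2 and FER1 where measured. Unnamed probe sets and members of further lists were chosen after their values were seen. Of 24 fixed lists with 372 members, 39 members had a probe set of their own and 333 did not. The lists of iron uptake, coumarins, root hairs, auxin, cell division and photosynthesis could be tested, and 18 could not. A further 20 lists were written after the probe annotation was seen and were not part of the plan.

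Whether replicate numbers pair arrays was checked by correlating the deviations of same-numbered arrays from their group means. Among the groups compared, all 3 correlations were over 0.1 between Col-0 with and without Fe (0.26, 0.11 and 0.15) and between Col-0 and CsUBC13-OE without Fe (0.30, 0.20 and 0.11), so the numbers pair these arrays and blocked values are given there. They came from the data, since the labels do not say what a number shares.

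Each fit was tested on simulated data with independent noise, 200 of 22746 probe sets changed and a list of 10 genes raised 1.5-fold. With fewer true changes the adjusted threshold is stricter, and the shares recovered would be lower. For the Fe response of Col-0 it recovered 29.9% of 1.5-fold, 76.1% of 2-fold and 93.9% of 4-fold changes. For CsUBC13-OE against Col-0 it recovered 65.7% of 2-fold changes at either supply, and for ubc13A against Col-0 59.7% with Fe and 68.7% without. For the difference in Fe response of CsUBC13-OE it recovered 28.4% of 2-fold changes and for that of ubc13A 34.3%.

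The alternatives were quantile normalization, centring arrays on the median, leaving out the dimmest 40% of probe sets, moderation with a trend and robust to outlying variances, replicate blocks, pseudocounts of 1 and 64, array weights, a test against a 1.2-fold change, only the arrays of a contrast, an estimated correlation for lists, and leaving out each array in turn. Fits without the arrays of 1 genotype, blocks within a contrast, slopes over probe sets called in the genotype on neither axis, the further lists, averages over both supplies, and the overlap of genotype effects between comparisons without a common array were added after the data were seen.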

Results

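Root RNA of 3 Arabidopsis thaliana genotypes was measured on 18 single-colour Affymetrix ATH1 arrays, 3 biological replicates for each of 6 groups. The genotypes were the Col-0 wild type, a Col-0 line overexpressing the cucumber UBC13 gene (CsUBC13-OE) and a mutant of the Arabidopsis gene UBC13A (ubc13A). UBC13 is a ubiquitin-conjugating enzyme. Seedlings 10 days old were moved to medium with or without the iron chelate FeEDTA, and roots were harvested 3 days later. Arrays carry no read depth, and their number limits the precision. The median standard error of a log2 difference between 2 groups was 0.18, and that of a difference between 2 Fe responses was 0.26. Correlations between arrays ran from 0.958 to 0.992, and no pair of arrays was identical. Along the first principal component, which held 26.0% of the variance, every array without Fe lay above every array with Fe.

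**Figure D1:**
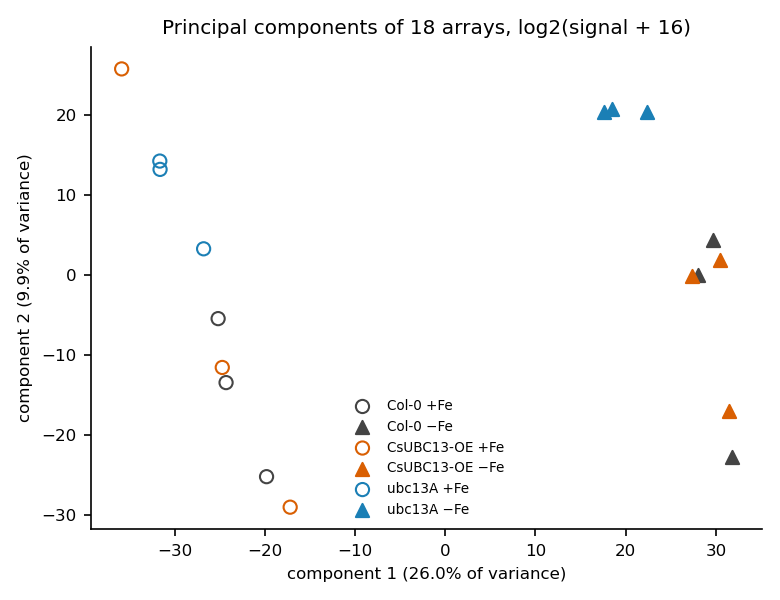
Scores of the 18 arrays on the first and second principal components of log2(signal + 16), which held 26.0% and 9.9% of the variance; each point is 1 array, open circles are roots with Fe and filled triangles roots without Fe. Scores on the first component ran from -35.9 to -17.2 with Fe and were above 0, up to 31.7, without Fe.

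The first question was whether the UBC13 transcripts differed between the lines. Neither UBC35, the Arabidopsis UBC13A gene, nor UBC36, its close relative, had a probe set of its own, and the cucumber transgene was not measured here. The probe set 264303_s_at is annotated to both genes together, so its signal cannot be given to either. Its signal was 3782 ± 478 with Fe and 3615 ± 476 without Fe in Col-0 (SD, n = 3). In CsUBC13-OE it was 4089 ± 210.2 and 4233 ± 433, and in ubc13A 2879 ± 484 and 2725 ± 312. For 264303_s_at the log2 difference of ubc13A from Col-0 was -0.40 at both supplies (SE 0.15) and did not pass limma's test (adjusted p = 0.393 with Fe and 0.308 without). Because the probe set is shared and the position of its probes relative to the mutation is not given, this neither bears out nor contradicts the genotype labels.

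Removing Fe from Col-0 roots raised genes of iron acquisition and of coumarin synthesis. S8H (AT3G12900), which makes the iron-mobilizing coumarin fraxetin, rose from a signal of 14.2 ± 7.4 to 8537 ± 1239 (SD, n = 3), a log2 change of 8.16 (SE 0.28, adjusted p = 1.63e-10). The cytochrome P450 gene CYP71B5 rose by 6.74 on the log2 scale, MTP8 (AT3G58060), a vacuolar metal transporter, by 4.92, and BHLH101, a transcription factor of the iron deficiency response, by 4.63. With Fe, the mean signals of S8H, CYP71B5 and BHLH101 were at most 23.2 in all 3 genotypes and are not shown to lie above background. The sizes of their changes in each genotype are therefore set in part by the pseudocount. Among the genes that fell were AT1G52820, a member of the 2-oxoglutarate-dependent dioxygenase family (-3.83, SE 0.42), and SAPX, which encodes the stromal ascorbate peroxidase (-2.14, SE 0.26). Without Fe, the mean signal of AT1G52820 was at most 14.8 in all 3 genotypes, so the size of its fall in each has the same limit.

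All 5 measured members of the fixed list of iron uptake genes and their regulators rose in Col-0. They were BHLH101, IMA1 (3.58), which encodes a small iron-regulated peptide, BTSL1 (2.33) and BTSL2 (1.93), which encode ubiquitin ligases that restrain the response, and the transcription factor gene PYE (1.58). The list had a median change of 2.33 and camera's adjusted p was 7.77e-21 with the preset correlation and 7.16e-06 with an estimated correlation. All 4 measured coumarin genes rose as well, with a median of 3.16, and the adjusted p was 7.77e-21, and 9.7e-06 with an estimated correlation. Besides S8H these were the beta-glucosidase gene BGLU42 (3.88), F6'H1 (2.44) and COSY (1.31), which encode enzymes of scopoletin synthesis. IRT1, FRO2, FIT and FER1 had no probe set of their own and are not reported.

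Of 8 auxin genes only GH3.3, which encodes an enzyme that conjugates auxin to amino acids, rose in Col-0 (1.81, SE 0.30). IAA20 stood at 0.80, IAA29 at 0.50 and LBD16 at 0.32 without passing the test. The auxin list was called higher (adjusted p = 0.0142), but not with an estimated correlation, where the adjusted p was 0.11; adjusted over the list alone, 2 members rose. The 4 photosynthesis genes of green tissue were called lower as a list, with a median of -0.38 (adjusted p = 0.0218, and 0.218 with an estimated correlation). None of them fell over all genes, and 1 fell when adjusted over the list alone. RCA, encoding Rubisco activase, stood at -0.59, PSAE-1 at -0.44, LHCB4.1 at -0.32 and PRK at -0.23. The root hair list (median -0.25, adjusted p = 0.102) and the cell division list (median -0.23, adjusted p = 0.124) were not called, and XTH26, a root hair xyloglucan enzyme, stood at -1.11 without passing the test. Outside the testable lists, the zinc transporter gene ZIP9 (0.81) and CCS (0.71), which encodes the copper chaperone of superoxide dismutase, rose.

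The other genes named by the fixed rule in Col-0 included AT3G61930 (5.47), AT1G12030 (3.97) and AT4G19370 (3.93) among those rising. Falling genes were AT2G36885 (-2.54), AT3G45710 (-2.40), AT1G74490 (-2.13), AT3G49160 (-2.08), AT3G49960 (-2.07) and AT5G22390 (-2.01). The Col-0 signals of AT3G49160 (8.5) and AT5G22390 (17.3) without Fe, and of AT1G12030 (6.9) with Fe, are not shown to lie above background. The sizes of these 3 changes are therefore set in part by the pseudocount. AT3G45710 belongs to the nitrate and peptide transporter family, AT3G49160 to the pyruvate kinases and AT3G49960 to the peroxidases. In all, limma with Benjamini-Hochberg adjustment called 970 of 22746 probe sets, 503 higher and 467 lower without Fe, of which 391 changed at least 2-fold and 497 named 1 gene. With the replicate number as a block in a fit of these 6 arrays alone, 405 were called, and 51.9% of calls were higher as deposited against 63.2% after centring each array on its median. A test against a 1.2-fold change called 443, and the 6 arrays without a block called 595.

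**Figure D2:**
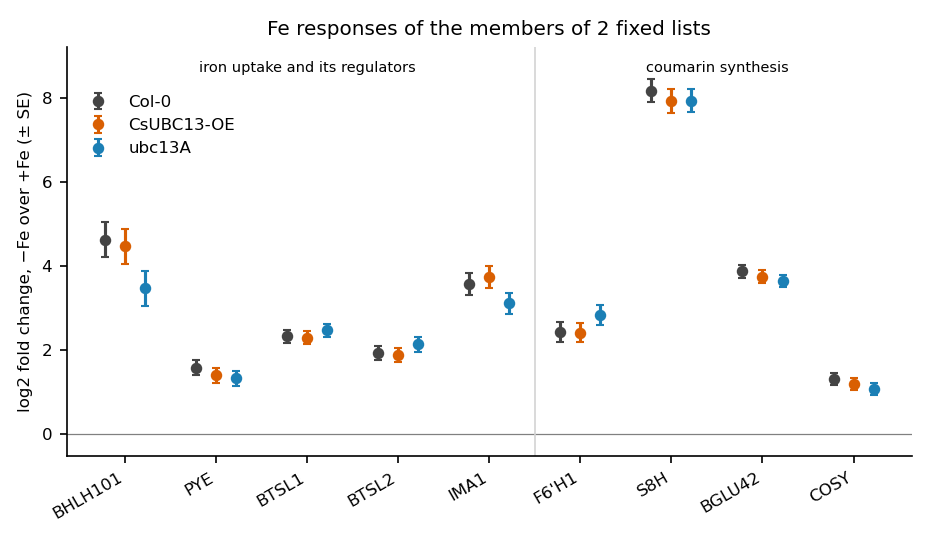
Log2 fold change without Fe over with Fe of the 9 measured genes of the iron uptake and coumarin lists, in Col-0, CsUBC13-OE and ubc13A (points, limma estimates from 3 arrays per group; bars, standard error). Every value was above 1, from 1.08 for COSY in ubc13A to 8.16 for S8H in Col-0.

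Removing Fe from CsUBC13-OE roots raised the same list members as in Col-0. S8H (AT3G12900) rose by 7.92 on the log2 scale (SE 0.28, adjusted p = 2.55e-10), CYP71B5 by 6.62, MTP8 (AT3G58060) by 4.82 and BHLH101 by 4.46. AT5G38820, of the amino acid transporter family, rose by 4.26. AT1G52820 fell by 4.3, and PDF2.1, which encodes a defensin-like peptide, fell by 2.13 (SE 0.23).

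All 5 iron uptake genes rose in CsUBC13-OE, with a median of 2.29 (adjusted p = 1.68e-20, and 7.73e-06 with an estimated correlation); IMA1 rose by 3.74, BTSL1 by 2.29, BTSL2 by 1.89 and PYE by 1.40. All 4 coumarin genes rose, with a median of 3.08 (adjusted p = 1.68e-20, and 1.06e-05 with an estimated correlation), among them BGLU42 (3.75), F6'H1 (2.42) and COSY (1.2). The photosynthesis list was called lower (median -0.76, adjusted p = 0.000117), but not with an estimated correlation, where the adjusted p was 0.0761. RCA (-0.94) and LHCB4.1 (-0.89) fell, while PSAE-1 stood at -0.62 and PRK at -0.33; adjusted over the list alone 3 members fell. GH3.3 rose by 1.90, but the auxin list was not called (adjusted p = 0.0954; its median of -0.02 and its mean of 0.27 differed in sign). AUR2, an Aurora kinase of dividing cells, fell by 0.46; the cell division list (median -0.30, adjusted p = 0.0907) and the root hair list (median -0.38, adjusted p = 0.0822) were not called. ZIP9 (1.09) and CCS (0.62) rose.

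The remaining genes named by the rule in CsUBC13-OE were AT3G61930 (5.67), AT4G19370 (3.82) and AT1G49000 (3.81) among those rising. Those falling were AT5G01740 (-2.38), AT2G36885 (-2.18), AT3G45710 (-2.16), the GRAS family gene AT3G13840 (-2.10), SAPX (-2.04) and AT3G49160 (-2.03). Without Fe the signals of AT3G13840 (8.6) and AT3G49160 (11.7) are not shown to lie above background, which limits the sizes of their falls. The test called 984 probe sets, 504 higher and 480 lower, of which 426 changed at least 2-fold and 482 named 1 gene. The share of higher calls was 51.2% as deposited and 59.8% after centring on the median. A test against a 1.2-fold change called 459, and the 6 arrays fitted alone called 438.

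Removing Fe from ubc13A roots also raised iron uptake and coumarin genes. S8H (AT3G12900) rose by 7.93 on the log2 scale (SE 0.28, adjusted p = 2.5e-10), CYP71B5 by 6.38, MTP8 (AT3G58060) by 4.32 and AT3G07720, a kelch repeat gene, by 4.05. AT1G52820 fell by 2.90 (SE 0.42) and AT5G57785 fell by 2.27 (SE 0.27).

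All 5 iron uptake genes rose in ubc13A, with a median of 2.47 (adjusted p = 8.29e-19, and 1.27e-05 with an estimated correlation); BHLH101 rose by 3.47, IMA1 by 3.11, BTSL1 by 2.47, BTSL2 by 2.14 and PYE by 1.33. All 4 coumarin genes rose, with a median of 3.24 (adjusted p = 2.02e-19, and 1.31e-05 with an estimated correlation), among them BGLU42 (3.64), F6'H1 (2.84) and COSY (1.08). GH3.3 rose by 1.22, a call that ended with the replicate number as a block and in the fits without any 1 of the arrays other than ubc13A replicate 3 without Fe. The auxin list was not called (adjusted p = 0.453; median -0.07, mean 0.11). The photosynthesis list (median -0.29, adjusted p = 0.28), the root hair list (median -0.24, adjusted p = 0.554) and the cell division list (median -0.16, adjusted p = 0.315) were not called either, with RCA at -0.47, XTH26 at -0.54 and AUR2 at -0.16. ZIP9 (1.24) and CCS (0.58) rose.

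The remaining genes named by the rule in ubc13A were AT3G61930 (5.57), AT5G38820 (4.04) and AT1G73120 (3.99) among those rising. Those falling were AT4G04990 (-2.27), AT5G22390 (-1.80), AT2G34610 (-1.77), AT5G01740 (-1.75), AT2G41810 (-1.74) and AT1G70880 (-1.72). Without Fe the signals of AT4G04990 (18.7), AT5G22390 (18.4) and AT1G70880 (8.1) are not shown to lie above background, which limits the sizes of their falls. The AT1G70880 call ended in the fits without any 1 of the arrays other than ubc13A replicate 2 without Fe. The test called 847 probe sets, 476 higher and 371 lower, of which 326 changed at least 2-fold and 420 named 1 gene. The share of higher calls was 56.2% as deposited and 68.6% after centring on the median; a test against a 1.2-fold change called 339, and the 6 arrays fitted alone called 419.

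The Fe responses of the 3 genotypes rest on separate arrays. Of the probe sets called higher in Col-0, 405 were also called higher in CsUBC13-OE and 352 in ubc13A, where independent lists of these sizes would share 11.1 and 10.5. Of those called lower in Col-0, 290 were also lower in CsUBC13-OE and 189 in ubc13A, against 9.9 and 7.6. In all 3 genotypes 327 were called higher and 162 lower. Across the 970 probe sets called in Col-0, the log2 changes in CsUBC13-OE followed those in Col-0 with a slope of 0.97 (r = 0.982) and those in ubc13A with a slope of 0.84 (r = 0.950). The slopes had an SD of 0.033 and 0.015 over the 9 pairs of arrays of the other genotype. These pairs share arrays and the Col-0 changes were held fixed, so this SD is not the standard error of a slope. Picking probe sets in Col-0 lowers a slope by chance, and picking them in the other genotype raises it. Over the probe sets called in the other genotype the slopes were 1.03 and 0.94. Over those called in the genotype on neither axis, a choice made after the data were seen, they were 1.002 and 0.873. For ubc13A this slope was 0.931 over the rising and 0.722 over the falling ones. Same-numbered Col-0 and CsUBC13-OE arrays without Fe deviate together, so this choice is not fully free of noise shared with Col-0. These are relations across probe sets, which are not independent replicates.

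**Figure D3:**
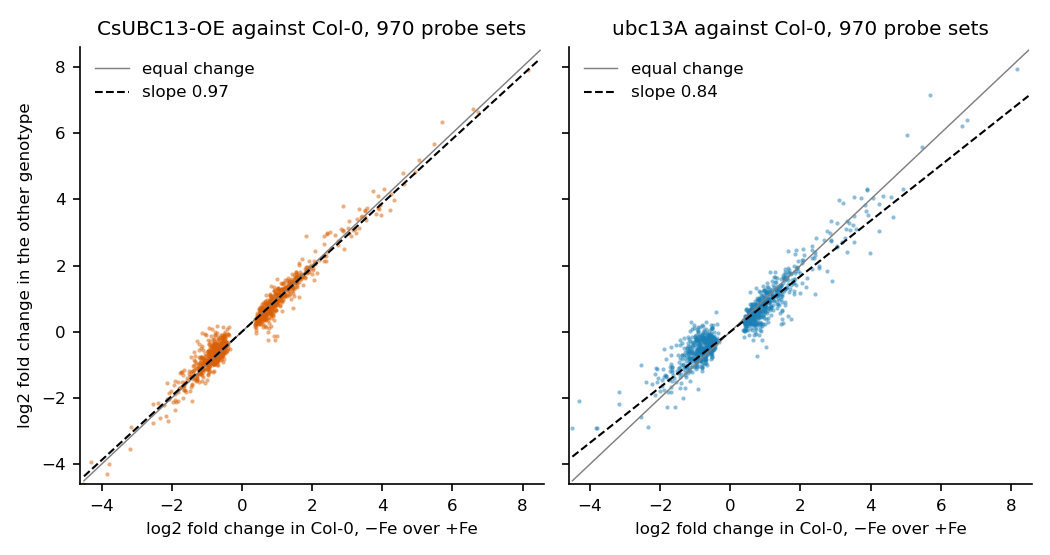
Log2 fold change without Fe over with Fe in CsUBC13-OE (left) and ubc13A (right) against that in Col-0, for the 970 probe sets called in Col-0; each point is 1 probe set, the solid line marks equal change and the dashed line the slope through the origin. The slope was 0.97 for CsUBC13-OE and 0.84 for ubc13A.

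Whether overexpression changed the Fe response itself was tested as the difference of the responses of CsUBC13-OE and Col-0. AT2G06140, annotated as a pseudogene, was the 1 probe set called: its signal without Fe against with Fe differed between the lines by -1.40 (SE 0.18, adjusted p = 0.0209). The signal of AT2G06140 was 31.7 ± 4.4 in CsUBC13-OE with Fe (SD, n = 3) and at most 4.9 on average in the other groups, close to the lowest values of the arrays. The call ended in 11 of the 12 fits that left out 1 array, and stood only without Col-0 replicate 3 without Fe. With the replicate number as a block its adjusted p was 0.0549 and 0 probe sets were called. With that block the photosynthesis list was called lower by camera with the preset correlation (adjusted p = 0.0424, against 0.0558 without the block). With an estimated correlation and no block its adjusted p was 0.775. Without the block none of the 6 fixed lists was called: the iron uptake list had a median difference of -0.04 (adjusted p = 0.798) and the coumarin list one of -0.12 (adjusted p = 0.589). BHLH101 differed by -0.16, IMA1 by 0.16, S8H by -0.25 and F6'H1 by -0.02, none past the test. The medians were 0.01 for the root hair list (0.802), -0.08 for the auxin list (0.589), -0.07 for the cell division list (0.798) and -0.27 for the photosynthesis list (0.0558), with the adjusted p in parentheses. At an unadjusted p under 0.05 stood 605 probe sets.

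Whether loss of UBC13A changed the Fe response was tested in the same way. BHLH101 responded less in ubc13A by a log2 difference of -1.16, and AT1G12030 by -1.60, while the fall of AT2G36885 was smaller by 1.53 and that of AT1G74490 by 1.02, but none of these differences passed the test. The sizes for BHLH101 and AT1G12030 rest on signals with Fe that are not shown to lie above background: 6.8 in Col-0 and 23.0 in ubc13A for BHLH101, and 6.9 and 18.6 for AT1G12030. Without Fe alone the 2 genes were lower in ubc13A by log2 differences of -0.47 and -1.06, neither past the test. With limma, 0 probe sets were called; the smallest adjusted p was 0.161, and 1254 stood at an unadjusted p under 0.05. The iron uptake list had a median difference of -0.25 and the coumarin list one of -0.23 (adjusted p = 0.46 and 0.5). The root hair list stood at 0.24 (0.46), the auxin list at -0.28 (0.317), the cell division list at 0.12 (0.749) and the photosynthesis list at 0.11 (0.46), with the adjusted p in parentheses. On simulated data, the test of this difference recovered 34.3% of 2-fold and 87.9% of 4-fold differences, so that smaller ones were mostly not detectable with 3 arrays per group.

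With Fe, CsUBC13-OE roots differed from Col-0 roots in 3 probe sets. The pseudogene AT2G06140, at the low signals given above, was higher by 1.43 (SE 0.12, adjusted p = 9.4e-05). The unnamed probe set 260813_at was higher by 1.73 (SE 0.12, adjusted p = 7.38e-06), with signals of 877.6 ± 40.3 against 254.2 ± 30.8 (SD, n = 3). A further unnamed probe set, 252468_at, was lower, with a log2 difference of -1.53 (SE 0.18, adjusted p = 0.0032). None of the 6 fixed lists was called: the iron uptake list had a median of 0.09, the coumarin list 0.02, the root hair list -0.04, the auxin list 0.08, the cell division list -0.04 and the photosynthesis list 0.08, with adjusted p between 0.883 and 0.952. At an unadjusted p under 0.05 stood 633 probe sets, and the 6 arrays fitted alone called 0.

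Without Fe, 252468_at (-1.86, SE 0.18, adjusted p = 0.000526) and 260813_at (1.2, SE 0.12, adjusted p = 0.000526) again differed between CsUBC13-OE and Col-0. AT1G09360 was lower by a log2 difference of -0.63 (SE 0.09, adjusted p = 0.046), but its mean signals ran from 2.1 to 14.0 over the 6 groups and are not shown to lie above background. With the replicate number as a block over all arrays its adjusted p was 0.0671, and 2 probe sets were called in place of 3. The 2 were 252468_at (limma adjusted p = 0.00258) and 260813_at (0.00141). In a blocked fit of the 6 arrays alone, which leaves few residual degrees of freedom, 0 were called. There the adjusted p was 0.626 for 252468_at and 0.69 for 260813_at and AT1G09360, while the estimates stayed at -1.86, 1.2 and -0.63. None of the fixed lists was called: the medians were 0.01 for iron uptake, -0.11 for coumarin, -0.06 for root hair, -0.02 for auxin, 0.04 for cell division and -0.24 for photosynthesis, with adjusted p from 0.102 to 0.898. At an unadjusted p under 0.05 stood 792 probe sets.

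The ubc13A arrays stood apart from the other 12 in some control probe sets, of bacterial transcripts and of 25S ribosomal RNA, which is a plant transcript. The bacterial dap 5-prime control had signals of 240.5 to 436.8 on them and 26.6 to 115.4 on the others, and the 25S ribosomal RNA control 277.7 to 1019.4 against 2104.1 to 12626.1. A sign of RNA quality, the ratio of the 3-prime to the 5-prime actin control, was 2.01 to 2.73 in ubc13A with Fe and 1.84 to 1.86 without, and 1.69 to 2.12 and 1.6 to 2.09 in Col-0; that of GAPDH was 1 to 1.11 and 0.87 to 1.03 in ubc13A, and 0.87 to 0.97 and 0.81 to 0.96 in Col-0. Each genotype difference of ubc13A below is therefore also a difference between arrays that differ in these controls, and processing and genotype cannot be told apart.

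With Fe, ubc13A roots differed from Col-0 roots in 3 probe sets. AT3G20760, a component of the Smc5/6 complex of genome maintenance, was higher by 1.11 (SE 0.12, adjusted p = 0.00104), with signals of 28.4 ± 4.7 against 4.57 ± 1.8, close to the lowest values of the arrays, and the peroxidase gene AT4G11290 was lower at a log2 difference of -0.86 (SE 0.13, adjusted p = 0.0428). The unnamed 260813_at was higher by 1.62 (SE 0.12, adjusted p = 1.78e-05). The AT4G11290 call ended in the fits without any 1 of the arrays other than ubc13A replicate 2. The photosynthesis list was lower (median -0.34, adjusted p = 0.00665, and 0.383 with an estimated correlation), with PSAE-1 at -0.49, PRK at -0.39, LHCB4.1 at -0.29 and RCA at -0.28, none past the test. The iron uptake list (median -0.03, adjusted p = 0.53; mean 0.03), the coumarin list (0.14, 0.954), the root hair list (-0.30, 0.121), the auxin list (0.25, 0.159) and the cell division list (-0.08, 0.571) were not called. With Fe, 2238 probe sets stood at an unadjusted p under 0.05; leaving out ubc13A replicate 2 with Fe gave 7 calls. Higher calls made up 66.7% of the 3 as deposited and 2 of 10 calls after centring on the median, and the number rose to 32 without the dimmest 40% of probe sets.

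Without Fe, a glucosyltransferase gene and a marker of oxidative stress were among the genes lower in ubc13A than in Col-0. UGT84A1, which encodes a glucosyltransferase acting on hydroxycinnamic acids, had a signal of 38.2 ± 4.0 against 185.7 ± 37.1 (SD, n = 3), a log2 difference of -1.88 (SE 0.25, adjusted p = 0.0147). AT2G21640, a marker of oxidative stress, was lower (-1.21, adjusted p = 0.0292), as were AT4G19200 (-0.70) and AT1G09360 (-0.62), the latter with mean signals of at most 14.0. AT5G62340, of the pectin methylesterase inhibitor family, was higher (1.52, adjusted p = 0.0345), as was psaB (1.19, adjusted p = 0.0292), which encodes a core subunit of photosystem I. The unnamed 250083_at (-2.29), 250558_at (-1.60) and 251827_at (-1.35) were lower and 260813_at (1.19) higher; 264273_s_at, which is given to several genes, was higher by 1.01.

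A list of 8 flavonoid and anthocyanin genes was lower in ubc13A without Fe, with a median of -0.84 (camera, adjusted p = 2.79e-09, and 0.00312 with an estimated correlation). No member passed the test over all genes and 6 passed it adjusted over the list alone; DFR, which encodes dihydroflavonol reductase, stood at -2.82, AT5MAT at -1.40, UF3GT at -1.02 and UGT78D2 at -0.88. Of 69 genes of the chloroplast genome, 1 was higher over all genes and 29 over the list alone, and the list was called higher (median 0.60, adjusted p = 5.49e-11), but not with an estimated correlation, where the adjusted p was 0.229. Both lists were written after the probe annotation was seen and were not part of the plan. The 6 fixed lists were not called: the medians were -0.43 for iron uptake, -0.05 for coumarin, 0.02 for root hair, 0.02 for auxin, 0.03 for cell division and -0.19 for photosynthesis, with adjusted p from 0.129 to 0.744.

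The test called 11 probe sets, 4 higher and 7 lower, with 2524 at an unadjusted p under 0.05. The calls of AT5G62340, AT4G19200 and AT1G09360 ended whichever array was left out, those of psaB and AT2G21640 unless it was ubc13A replicate 3, and that of UGT84A1 unless it was replicate 3 of either genotype. The count depended on the arrays and settings: it was 2 without Col-0 replicate 1 or without ubc13A replicate 2, 3 without ubc13A replicate 1, 4 without Col-0 replicate 2 and 5 without Col-0 replicate 3. It was 126 without the dimmest 40% of probe sets and 0 when the 6 arrays were fitted alone. Higher calls made up 36.4% as deposited and 23.5% after centring on the median.

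**Figure D4:**
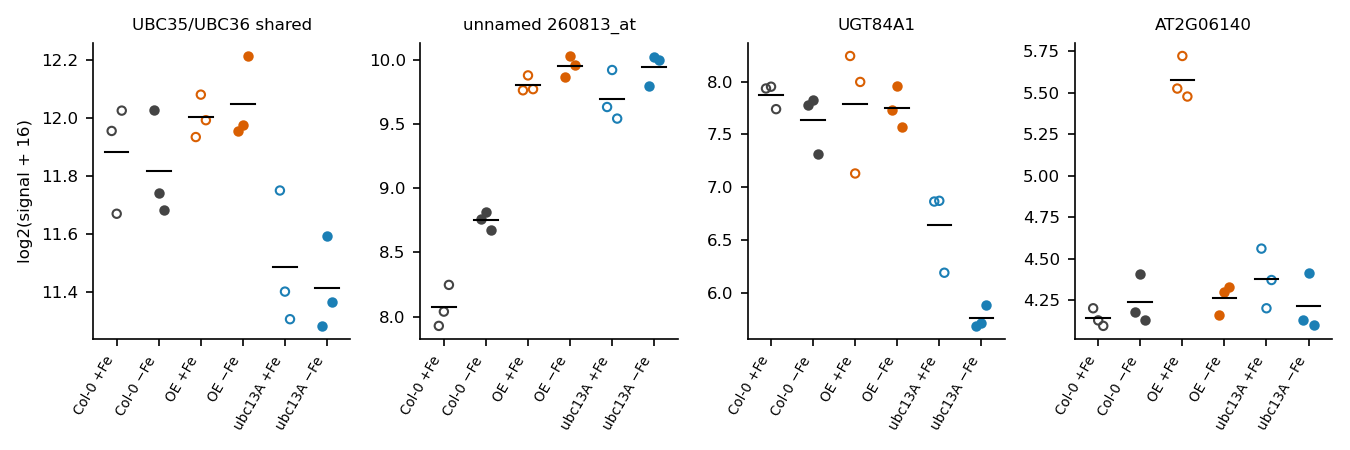
Log2(signal + 16) of 4 probe sets on each of the 18 arrays (points; open with Fe, filled without Fe) with the group means (lines). For 260813_at the means were 8.07 and 8.75 in Col-0 and at least 9.70 in both other genotypes, and for UGT84A1 they were 6.64 and 5.76 in ubc13A and at least 7.64 elsewhere.

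The genotype effects of CsUBC13-OE and ubc13A were compared at each supply. With Fe, 260813_at was the 1 probe set called in both, and without Fe 260813_at was higher and AT1G09360 lower in both, the latter at mean signals of 2.1 to 14.0, which are not shown to lie above background. Because both comparisons use the same Col-0 arrays, all groups were simulated without a genotype effect, with simulated Col-0 arrays shared by both comparisons. The simulated overlap was 0 in each of 100 draws. Unchanged groups give almost no calls, so this overlap decides nothing about noise of the shared Col-0 arrays. Independent lists would share 0.00018 higher probe sets. The correlation of the log2 differences across probe sets was 0.341 with Fe (simulated 0.499) and 0.449 without Fe (simulated 0.500), and the covariance 0.0231 and 0.0317 (simulated 0.0292 for both). The covariance differed from the simulated one by -0.006 with Fe and 0.0025 without (SD of the simulations 0.000518 and 0.000581). The simulation took all groups as independent and equally variable; with the variance of each group and the pairing by replicate number, computed after the data were seen, the differences were 0.0013 and 0.0061. The sign with Fe thus depended on this choice, and no shared effect is read from it. Without Fe the covariance was above the value for unchanged groups under both choices, and the cause was not tested. With 3 control arrays no split left 2 for each side, but a comparison with Fe and another without Fe share no array. In both such pairs 260813_at was the 1 probe set called, so its call in both lines does not rest on the same Col-0 arrays. Col-0 plants were still the reference in both, and their arrays with and without Fe deviate together by number. A difference that lies in the Col-0 samples themselves is therefore not excluded. The correlations over all probe sets were 0.026 and 0.027 in these pairs. The overlap at AT1G09360 could not be measured apart from the shared controls.

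**Figure D5:**
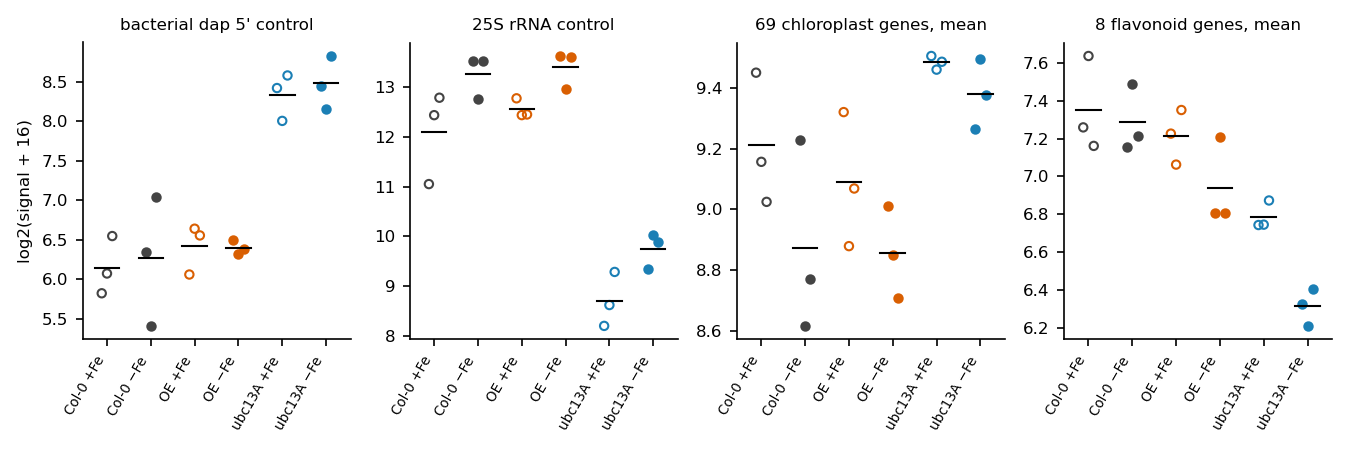
Log2(signal + 16) on each of the 18 arrays (points; open with Fe, filled without Fe; lines, group means) of the bacterial dap 5-prime control, the 25S ribosomal RNA control, and the means of 69 chloroplast and 8 flavonoid genes. The group means of the dap control were 8.33 and 8.48 in ubc13A and at most 6.42 elsewhere.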

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

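The tests of the chloroplast, flavonoid and falling probe sets below were chosen after the results were seen, and the counts of other splits were planned.

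AT2G06140 was singled out because its Fe response differed between CsUBC13-OE and Col-0 in a test of the difference itself (log2 difference -1.40, SE 0.18, limma adjusted p = 0.0209). Its signal was 31.7 ± 4.4 in CsUBC13-OE with Fe and 1.67 to 4.9 in the other groups, where the arrays barely separate signal from 0. Of 100 splits of the arrays, 19 called at least the 1 probe set of the real one, so chance was not excluded. The highest other split called 100, many times the real count, which points to a structure of the samples other than the groups.

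Some of the bacterial control probe sets, which no comparison used, gave a signal on all 6 ubc13A arrays above that of all other 12 arrays, among them the 5-prime and middle ones of dap and thr. The ratio of the means over the Col-0 arrays was 5.23 for the dap 5-prime and 5.29 for the thr 5-prime probe set, 2.31 for the middle dap and 2.32 for the middle thr probe set. For the 3-prime probe sets AFFX-r2-Bs-dap-3_at and AFFX-r2-Bs-thr-3_s_at the ratio was 1.55 and 1.43 and the ranges overlapped, but for a further one, AFFX-DapX-3_at, it was 1.82 and they did not (538.4 to 888.4 against 265 to 478.7). The ranges of all lys, phe, bio and cre probe sets overlapped those of the other 12 as well. Their ratios over the Col-0 arrays were nonetheless above 1 for every bio (1.19 to 1.55) and phe (1.17 to 2.06) probe set. For lys they ran from 0.959 to 1.62 and for cre from 0.971 to 1.15. The thr 5-prime signals ran from 68.6 to 134.9 on the ubc13A arrays and from 2.9 to 31.2 on the other 12. The latter lie close to the lowest values of the arrays, so the ratio of 5.29 is only approximate.

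As a list, chloroplast transcripts were higher in ubc13A than in Col-0 without Fe (median of 69 genes 0.60, camera adjusted p = 5.49e-11), but not with an estimated correlation, where the adjusted p was 0.229. More green tissue in the samples would raise nuclear photosynthesis genes too, but their median was -0.06. Its upper 95% bound of 0.04 came from resampling the genes and leaves out the spread between arrays. Over the arrays without Fe the mean of that list was 7.82 (SD 0.20, n = 3) in ubc13A and 7.87 (SD 0.056, n = 3) in Col-0, so a small rise is not excluded. More carry-over of RNA without a poly(A) tail would raise 25S ribosomal RNA, but its log2 difference was -3.52 (SD 0.56). This control is among those that set the ubc13A arrays apart at both supplies, so it does not decide about carry-over. The dap 5-prime control, which has no plant target, differed by 2.21 on the log2 scale between the same arrays. These arrays thus differed in more than the transcripts of the plants. Whether separate processing raised the chloroplast transcripts stays open, because it cannot be told apart from genotype. An effect of UBC13A on these transcripts also stays open and was not tested apart from it.

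As a list, flavonoid genes were lower in ubc13A than in Col-0 without Fe (median of 8 genes -0.84, adjusted p = 0.00312 with an estimated correlation). A constant offset of all ubc13A arrays cancels in the difference of the Fe responses, which was -0.41 for the mean of the list (SE 0.19) and leaves separate processing open. The effect of genotype likewise stays open, as the ubc13A arrays stand apart in their controls at both supplies.

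Probe sets that fell without Fe fell less in ubc13A than in Col-0. Over the 480 called lower in CsUBC13-OE, which were not picked in Col-0, the mean change was -0.82 in Col-0 and -0.62 in ubc13A. The ratio of 0.75 (SE 0.04) argues against picking in Col-0. Same-numbered Col-0 and CsUBC13-OE arrays without Fe deviate together, however, so noise shared with Col-0 could still enter this choice. For the 504 called higher the ratio was 0.92 (SE 0.031), which argues against an equal compression of all changes. The actin 3-prime to 5-prime ratio fell with Fe removal in ubc13A, but with that ratio of each array in the fit the falls still stood at 0.73 (SE 0.058) and the rises at 0.88 (SE 0.034), which argues against RNA degradation as far as actin measures it and leaves a narrower gap between rises and falls. Growth or processing of Col-0 and CsUBC13-OE together and of ubc13A apart is not decided: same-numbered arrays of the former correlated at 0.30, 0.20 and 0.11 without Fe, but at 0.29, -0.03 and -0.02 with Fe. The values with Fe met the bound set down against it, but that bound was wrong and was changed after they were seen, because arrays processed together need not deviate by number; an effect of UBC13A coincides with it in the design and was not tested apart.

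For each Fe response the 10 splits of 6 arrays are too few for a share under 0.05; 1 split, the real one, reached the real count in each. The real counts were 970 in Col-0, 984 in CsUBC13-OE and 847 in ubc13A, and the highest other split called 2 in each. The same holds for the genotype comparisons. CsUBC13-OE called 3 against 1 in the highest other split with Fe and 3 against 2 without. For ubc13A with Fe, 2 of 10 splits reached the real count of 3, and without Fe the real 11 stood against 2. For the difference in Fe response of ubc13A, all 100 splits reached the real count of 0 (limma; 1254 at an unadjusted p under 0.05), as any split must, so this count decides nothing about chance. The highest other split called 165, which is the average genotype difference and marks that structure.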

How the results depend on the processing

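The fits without 1 genotype, the blocks within a contrast, the slopes over the probe sets called in the genotype on neither axis, and the averages over both supplies were added after the data were seen; the other alternatives were planned. Unless a fit has fewer arrays or probe sets, the cause was not tested.

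The number called for the Fe responses of Col-0, CsUBC13-OE and ubc13A was 443, 459 and 339 in a test against a 1.2-fold change, and 595, 438 and 419 with only the arrays of the contrast. Leaving out 1 array gave 657 to 810, 689 to 959 and 589 to 771. The replicate numbers pair the Col-0 arrays, and a block within that contrast left 405; a block over all arrays gave 1079, 1087 and 930. Normalization, filter, moderation, pseudocounts and weights kept these counts within 1.5 times.

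For CsUBC13-OE against Col-0, only the arrays of the contrast left 0 with Fe (limma; 633 at an unadjusted p under 0.05 over all arrays), and leaving out 1 array gave 3 to 4. Without Fe the count was 5 with array weights, 2 with the replicate block, 0 with a block within the contrast, and 2 to 3 without 1 array.

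For ubc13A against Col-0 with Fe the count of 3 became 11 with quantile normalization, 10 centred on the median, 32 without the dimmest 40%, 36 with trend and robust moderation, 6 with the replicate block, 6 and 19 with pseudocounts of 1 and 64, 11 with array weights, 0 with only the arrays of the contrast, and 2 to 7 without 1 array. Without Fe the count of 11 became, in the same order, 19, 17, 126, 106, 50, 7 and 76, 72, 0, and 2 to 10. It was 3 against a 1.2-fold change and 6 without the CsUBC13-OE arrays.

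The difference in Fe response of CsUBC13-OE was 0 without the dimmest 40%, with trend and robust moderation, the replicate block, pseudocounts of 1 and 64, a 1.2-fold test, only the arrays of the contrast, and without the ubc13A arrays (limma; 605 at an unadjusted p under 0.05 in the fit reported), and 0 to 1 without 1 array. That of ubc13A was 1 without the dimmest 40%, 1 with trend and robust moderation, 3 with array weights, and 0 to 0 without 1 array.

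Of the fixed lists, 2 in place of 4 were called for Col-0 with an estimated correlation, and 3 to 4 without 1 array; the ranges were 3 to 4 for CsUBC13-OE and 2 to 3 for ubc13A. For ubc13A with Fe, 0 in place of 1 were called with an estimated correlation, 2 with the replicate block, and 1 to 2 without 1 array, with 2 without Col-0 replicate 3. For the difference of CsUBC13-OE, 1 in place of 0 was called with the replicate block, with quantile normalization, without the dimmest 40%, and without Col-0 replicate 2 or CsUBC13-OE replicate 2 with Fe, or Col-0 replicate 3 or CsUBC13-OE replicate 2 without Fe (0 to 1). For CsUBC13-OE without Fe, 1 was called without the dimmest 40% and without Col-0 replicate 3 or CsUBC13-OE replicate 2 (0 to 1). For the difference of ubc13A 1 was called without Col-0 replicate 3 with Fe (0 to 1); CsUBC13-OE with Fe and ubc13A without Fe stayed at 0 to 0.

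The slope of CsUBC13-OE on Col-0 was 1.03 over probe sets called in the other genotype, 0.706 over all, and 1.01 over those rising in the genotype on neither axis. That of ubc13A was 0.94 and 0.591, 0.864 without the dimmest 40%, 0.859 with quantile normalization, 0.873 over those called in the genotype on neither axis, 0.931 over those rising in it and 0.722 over those falling. The overlap of the genotype effects without Fe was 1 in place of 2 with the replicate block.

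The averages over both supplies called 4 for CsUBC13-OE, which became 2 with a pseudocount of 1, 7 with array weights and 2 in the 1.2-fold test (3 to 5 without 1 array). The 165 of ubc13A became 473 without the dimmest 40%, 448 with trend and robust moderation, 252 with the block, 359 with a pseudocount of 64 and 12 in the 1.2-fold test. Leaving out 1 array gave 50 to 167: 50, 56 and 97 without Col-0 replicates 1, 2 and 3 with Fe, 73 and 100 without replicates 1 and 2 without Fe, 106 and 70 without ubc13A replicates 1 and 3 with Fe, and 87, 63 and 80 without its replicates 1, 2 and 3 without Fe.

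Of 3220 values of named genes under the alternatives, 3066 stayed on their side of the threshold, 148 lost it, 6 passed it and 0 reversed. The 6 were XTH26 and RCA in Col-0, which passed under 2 and 4 alternatives. No named gene of the iron uptake or coumarin lists lost its Fe call under any alternative. Signals near 0 limit dim genes such as AT2G06140.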

Other observations

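The averages over both supplies and their tests were added after the data were seen. The further lists here were written after the probe annotation was seen and were not part of the plan.

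Single genes outside the fixed lists moved with Fe in all 3 genotypes. Values follow the order Col-0, CsUBC13-OE, ubc13A. PUB23, a ubiquitin ligase gene, rose (1.83, 1.96 and 1.58), as did the glycosyltransferase genes UGT72E1 (2.07, 2.12 and 2.16) and UGT73D1 (1.57, 1.74 and 1.57), the serine carboxypeptidase-like gene scpl20 (1.75, 1.68 and 1.55) and SUFE2, of iron-sulfur cluster synthesis (1.29, 1.28 and 1.16). The sugar transporter gene SWEET17 rose (0.55, 0.53 and 0.61) while SWEET2 fell (-0.86, -1.01 and -0.85). CYP71B26 (-1.14, -1.50 and -1.47), scpl31 (-1.50, -1.17 and -0.69), rbcL, which encodes the large Rubisco subunit (-0.84, -0.91 and -0.86), and NAI2, of the endoplasmic reticulum body (-0.57, -0.42 and -0.42), fell.

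A list of 7 bHLH iron regulators was higher without Fe in each genotype, with medians of 0.26, 0.33 and 0.34 and camera adjusted p of 9.92e-05, 0.000459 and 3.83e-05 (0.0295, 0.0456 and 0.0143 with an estimated correlation). Lists of nuclear photosynthesis genes (-0.32, -0.61 and -0.23) and of endoplasmic reticulum body genes (-0.57, -0.29 and -0.42) were lower in each and autophagy genes (0.18, 0.23 and 0.21) higher, but none of these with an estimated correlation. The adjusted p with an estimated correlation was 0.318, 0.123 and 0.43 for nuclear photosynthesis, 0.111, 0.123 and 0.171 for the endoplasmic reticulum body, and 0.318, 0.276 and 0.171 for autophagy. The chloroplast genome list was lower in Col-0 (-0.32) and CsUBC13-OE (-0.25), with 0.318 and 0.457 for the same test. Of the 20 lists, 5, 5 and 8 were called for the Fe responses, 1 and 1 for CsUBC13-OE against Col-0 with and without Fe, 6 and 5 for ubc13A, and 1 and 3 for the differences in response of CsUBC13-OE and ubc13A. With an estimated correlation these became 1, 1 and 1, 0 and 0, 0 and 1, and 0 and 0. Without 1 array they ran, in the same order, from 4 to 5, 4 to 5 and 2 to 7, from 0 to 2 and 0 to 3, from 2 to 4 and 4 to 6, and from 0 to 2 and 0 to 5.

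Averaged over both supplies, 3 genes of anthocyanin synthesis were lower in ubc13A than in Col-0: DFR by a log2 difference of -2.37 (limma adjusted p = 0.0112), AT4G14090 by -1.31 (0.0468) and UF3GT by -1.30 (0.0147). Of the 8 members of the flavonoid list 2 were called lower, and the list was called (median -0.58, adjusted p = 5.18e-08, and 0.00515 with an estimated correlation). UGT84A1 (-1.56, 0.00167) and COR15A, a cold-response gene (-1.42, 0.0175), were lower too, and the chloroplast genes ndhD (1.49, 0.0234), psaB (1.15, 0.00167) and atpA (1.14, 0.0206) were higher, while cemA (-0.80, 0.0149) and petA (-0.68, 0.0206) were lower. Of the 69 members of the chloroplast list 14 were called higher and 2 lower, and the list was called higher (median 0.41, adjusted p = 5.18e-08), but not with an estimated correlation, where the adjusted p was 0.257. In all 165 probe sets were called, 81 higher and 84 lower, but this balance depended on scaling: it was 51 and 119 after centring on the median and 69 and 114 with quantile normalization. The count was not stable either, and ran from 50 to 167 when 1 array was left out. A single split of 100, the real one, reached the 165, and the highest other called 4. The other splits mix the genotypes and so put any difference between them into the spread, which lowers their counts. This count therefore does not exclude chance by itself. Separate processing of the ubc13A arrays, whose 25S ribosomal RNA and dap control signals differ from all others, is not excluded either. For CsUBC13-OE 4 were called: AT5G35940 (1.17, 0.0199), AT2G06140 (0.73, 0.00446), 252468_at and 260813_at. The flavonoid (median -0.24, adjusted p = 0.0436) and chloroplast lists (-0.08, 0.0274) were called lower in CsUBC13-OE too, but not with an estimated correlation (0.501 and 0.543). In ubc13A the lists of photosynthesis (-0.24, 0.00605), nuclear photosynthesis (-0.13, 0.00402), UDP-glycosyltransferases (-0.09, 0.000457), autophagy (-0.13, 0.0267) and tau glutathione transferases (-0.15, 0.037) were lower and that of the endoplasmic reticulum body higher (0.20, 0.0344). With an estimated correlation their adjusted p was 0.258, 0.347, 0.202, 0.272, 0.257 and 0.257. For the probe sets called in CsUBC13-OE, 3 of 100 splits reached the real count, and a split that put the arrays of replicate number 1 together called 49; with the replicate block the real split called 5.

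The array of CsUBC13-OE with Fe, replicate 2, scored 54.0 on the third principal component, and the other 17 arrays from -17.1 to 15.2. The 25S ribosomal RNA control was higher without Fe in each genotype on average: with and without Fe it ran from 2104.1 to 7053.7 and from 6947.3 to 11738.1 in Col-0, where the ranges overlap, from 5530.5 to 6992.1 and from 8018.8 to 12626.1 in CsUBC13-OE, and from 277.7 to 606.8 and from 634.3 to 1019.4 in ubc13A (n = 3 each).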
